A study of Mus musculus with 70 samples.

How the data were processed

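Messenger RNA of 70 mouse libraries was deposited as 1 table of FPKM values. Per the labels, the authors trimmed with cutadapt 1.12 and aligned to mm10 (GRCm38) with STAR 2. The tool that counted reads and its annotation are not stated. The table holds 21863 entries, of which 4 are the reporters and transgenes (EGFP, mCherry, frog MEK1 and human MKK6) and 21859 are genes. Of the gene IDs 21191 were found in GENCODE release 21, and 668 were not. More than 1 entry carries each of 24 symbols (50 entries), kept apart by ID.

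Against exon lengths of that release, 100% of the values under 1000 reads were whole reads within 0.02 of a read. The steps gave the depth of each library and, for an alternative, the reads per gene. Embryonic fibroblasts (from day 13.5) received 2 µg/mL doxycycline, and 100 ng of RNA went into a library against 50 ng for sorted cells (RNA integrity above 8). Drinking water held 10 mg/mL sucrose and doxycycline, at 0.2 mg/mL in the caMEK1 cages and 2 mg/mL in the caMKK6 and control cages, so kinase and dose differ together. Liver and colon libraries came from 16 animals per tissue, and both colours of an animal on doxycycline were sequenced.

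Groups were taken from the labels, 26 in all. Before the data were examined, the comparisons, the test, the alternatives, the gene lists and the rule for naming genes were fixed. Each tissue had 1 fit with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3 on log2(FPKM + 1), over genes at 1 FPKM or more in at least 3 MEF libraries or 2 liver or colon libraries. That left 11347, 10371 and 11542 genes in MEF, liver and colon, with 16, 14 and 14 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and rose, fell and changed are used of called genes and of lists that passed their test. Tests are two-sided. No p was adjusted across the 25 comparisons.

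MEFs on doxycycline at days 2, 4 and 7 were compared with MEFs of the same genotype without it at day 2, and the day 7 changes were subtracted between genotypes. In liver and colon, mCherry cells were compared with mCherry cells of control mice on doxycycline, GFP cells with GFP cells of the same genotype without doxycycline, mCherry with GFP cells of the same mice, and caMEK1 with caMKK6 mCherry cells.

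The rule named, for day 7 and for the mCherry and GFP comparisons of both kinases, 12 sentinel genes (Map2k1, Map2k6, Cdkn1a, Cdkn2a, Cdkn2b, Lmnb1, Mki67, Il6, Gdf15, Dusp6, Spry4 and 1 more) and the 8 largest rises and 8 largest falls among called genes whose groups separated completely and whose higher group averaged at least 5 FPKM, predicted genes and pseudogenes passed over. Elsewhere 3 rises and 3 falls were named. That further sentinel gene and 1 of the largest rises are not reported here. For the day 7 difference, with 4 groups, only the level was asked. From each list up to 4 called members served as examples.

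The 30 lists were written from general knowledge: SASP and secreted factors, CDK inhibitors, p53 targets, proliferation, ERK output, immediate early genes, heat shock, integrated stress response, interferon response, acute phase, hepatocyte functions, sterol and fatty acid synthesis, NRF2 targets, TGF-beta, Notch, lysosome, matrix and contractile, colon absorptive, colon goblet, colon stem and Wnt, fetal-like epithelium, and markers of endothelial, macrophage, lymphocyte, neutrophil, stromal, cholangiocyte and epithelial, enteroendocrine, erythroid and pancreatic enzyme cells. Some genes sit in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, with the Benjamini-Hochberg adjustment over the lists of a comparison. Counts are over all genes tested, and where no second count is given, the count adjusted over the list alone was the same. Overlaps, for comparisons that share no library, give the number chance predicts under Fisher's exact test (scipy 1.17.1).

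The alternatives were a pseudocount of 0.1, no filter, scaling to a common median, quantile normalization, a replicate block (the replicate number in MEFs, the animal in tissues), another comparator (untreated GFP cells of the same genotype for mCherry cells, control GFP cells on doxycycline for GFP cells), each library left out in turn, and the estimated correlation. Chosen after the data were seen were voom in limma on the recovered reads, a replicate block within genotype, subtraction of carried-over RNA from GFP cells, MEF libraries with the other transgene left out and caMEK1 liver animal 3 left out. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. No library was left out of the main results.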

Results

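Messenger RNA was sequenced in bulk in 70 mouse libraries of 26 groups, 18 with 3 libraries and 8 with 2. Doxycycline switches on a constitutively active kinase, MEK1 (caMEK1), which drives the ERK pathway and oncogene-induced senescence, or MKK6 (caMKK6), which drives p38 and stress-induced senescence. In chimeric mice mCherry marks the cells that can carry the active kinase and GFP the cells around them. Both were sorted from liver and colon epithelium. Control mice carry the colours without an active kinase. Mouse embryonic fibroblasts (MEFs) served as the in vitro counterpart. They gave 24 libraries in 8 groups of 3. Each kinase had cells without doxycycline at day 2 and with it at days 2, 4 and 7. Liver and colon gave 23 libraries each, in 9 groups of 2 or 3.

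Depth was read back from the deposited FPKM values, which were whole multiples of 1 read per library. MEF libraries held 10888915 to 17763531 reads in genes, liver libraries 9267318 to 14534256 and colon libraries 6671204 to 17396973. Between 8122 and 10790 genes reached 1 FPKM in a library. The 10 most abundant genes took 7.4% to 11.3% of the FPKM in MEFs, 9% to 15.1% in colon and 23.6% to 45.8% in liver. Libraries of the same group correlated across genes at r of 0.983 to 0.997 in MEFs, 0.918 to 0.995 in liver and 0.945 to 0.993 in colon. Genes are not independent replicates.

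The transgenes are listed under their species of origin, Xenopus for MEK1 and human for MKK6. In caMEK1 MEFs the frog sequence went from 3.07 ± 1.06 FPKM without doxycycline to 1079 ± 81.6 at day 2, 777 ± 112 at day 4 and 535 ± 97.6 at day 7 (SD, n = 3). In caMKK6 MEFs the human sequence stood at 970 ± 211, 747 ± 323 and 334 ± 290 FPKM on the same days. Colon mCherry cells held 261 ± 37.4 FPKM of the MEK1 transgene (n = 2) and 1825 ± 740 of the MKK6 transgene (n = 3). In liver mCherry cells the MEK1 transgene reached only 9.52 ± 4.33 FPKM (n = 3), and the MKK6 transgene was at 216 and 1211 FPKM in the pair of libraries. Levels below are means ± SD in FPKM, the group in question first and its comparator after vs. Log2 fold changes (log2FC) are of FPKM + 1 and carry their standard error. Adjusted p values beside a list's counts are from the list test, the 1 marked estimated being its value with an estimated correlation.

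**Figure D1:**
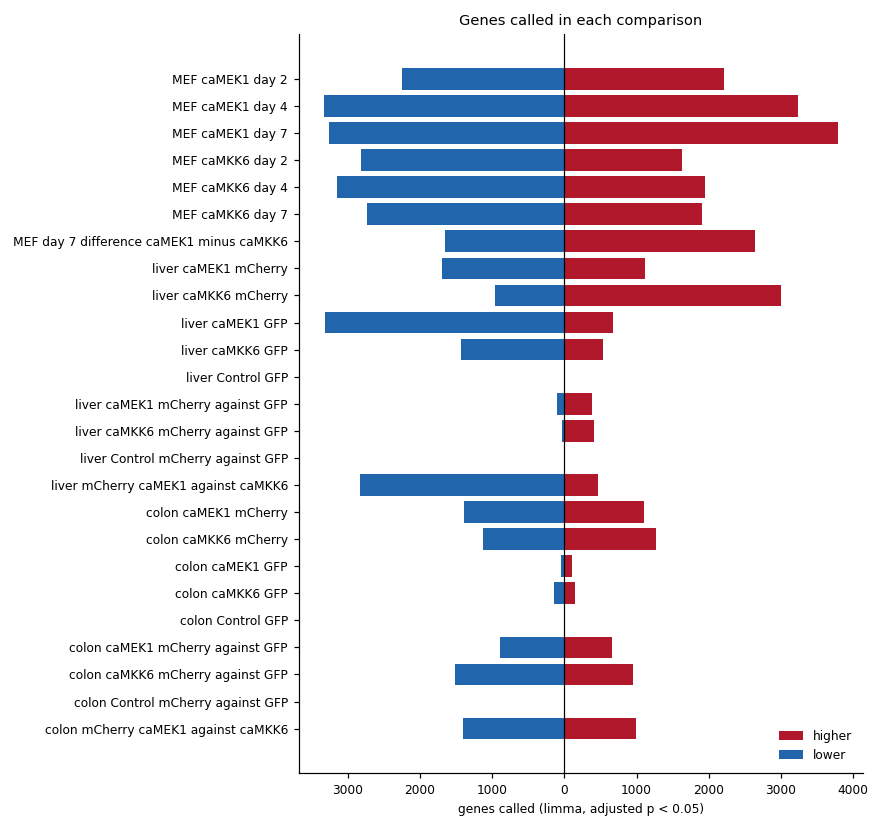
Genes called higher (red, to the right) or lower (blue, to the left) in each comparison at a limma adjusted p below 0.05, with the number of genes on the horizontal axis. The control comparisons of liver and colon stay at 11 genes or fewer, and the MEF comparisons with cells without doxycycline reach 4443 to 7042.

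In MEFs each day of caMEK1 was compared with the same cells without doxycycline (3 libraries per group). At day 2 the ERK phosphatase gene Dusp6 stood at 108 ± 4.99 vs 29 ± 1.66, log2FC 1.87 ± 0.10, adjusted p = 1.8e-11. The inhibitor Spry4 stood at 39.3 ± 1.65 vs 7.87 ± 0.842. The matrix protease Mmp3 reached 330 ± 46 vs 2.13 ± 0.874, log2FC 6.76 ± 0.71. The growth factor Areg reached 137 ± 12.9 vs 2.01 ± 0.552 and Spp1, which encodes osteopontin, 7712 ± 517 vs 425 ± 71.5. The semaphorin Sema7a rose from 1.9 ± 0.21 to 145 ± 4.72 FPKM. In the other direction, Ccn5 (0.46 ± 0.233 vs 35 ± 9.04), Aspn (0.377 ± 0.0605 vs 16.6 ± 0.295) and C1qtnf3 (3.17 ± 0.805 vs 51.1 ± 3.28) fell furthest. Doxycycline changed 4454 genes by day 2, of which 2208 rose and 2246 fell.

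ERK output genes rose at day 2, where 16 rose and 1 fell of 19 (adjusted p = 2e-09, adjusted p = 0.0024 estimated, 17 and 1 adjusted over the list alone). SASP genes, the secreted factors of senescent cells, included Areg, Mmp3 and Mmp10 (70 ± 13.1 vs 1.11 ± 0.24), and 19 rose and 8 fell of 31 (adjusted p = 0.00087, adjusted p = 0.13 estimated). Of NRF2 targets 8 rose, the antioxidant genes Srxn1 and Prdx1 among them, and 1 fell of 13 (adjusted p = 0.002, adjusted p = 0.37 estimated). Matrix and contractile genes went down: 0 rose and 13 fell of 14 (adjusted p = 5.6e-11, adjusted p = 0.047 estimated), with the collagen crosslinker Lox at log2FC -2.69 ± 0.12 and smooth muscle actin Acta2 at -2.52 ± 0.24. Of the immediate early genes 3 rose and 10 fell of 16 (adjusted p = 0.0016, adjusted p = 0.11 estimated, 3 and 13 adjusted over the list alone), Fos down by -1.57 ± 0.19 and Egr3 up by 3.25 ± 0.14. The CDK inhibitors Cdkn2b and Cdkn2a, which encode p15 and p16/p19, were already up at 0.97 ± 0.16 and 0.75 ± 0.14.

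At day 4 of caMEK1 Mki67, a marker of dividing cells, fell to 5.63 ± 0.927 vs 20.7 ± 2.34, adjusted p = 4e-08. Rrm2, which makes deoxynucleotides, fell to 32 ± 4.21 vs 130 ± 8.36 and Ccna2, a cyclin of DNA synthesis, to 9.22 ± 1.84 vs 34 ± 3.99. Cdkn2a (183 ± 12.2 vs 35.6 ± 6.99) and Cdkn2b (192 ± 27.2 vs 60.6 ± 15) rose. The largest rises were Mmp3 (579 ± 174 vs 2.13 ± 0.874) and a pair of genes of the nervous system, the neurofilament gene Nefl (132 ± 9.87 vs 0.37 ± 0.0602) and Nptx1 (227 ± 14.8 vs 1.68 ± 0.122). Ccn5, C1qtnf3 and Ptx3 fell furthest, at log2 fold changes of -4.55, -4.19 and -4.18. In all 6554 genes were called, 3231 up and 3323 down.

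Proliferation genes at day 4 moved almost as a block, where 1 rose and 32 fell of 33 (adjusted p = 3.5e-13, adjusted p = 0.29 estimated). ERK output genes rose (16 rose and 2 fell of 19, adjusted p = 1.5e-05, adjusted p = 0.035 estimated). For lysosome genes 12 rose and 1 fell of 16 (adjusted p = 1.9e-05, adjusted p = 0.29 estimated), with the protease Ctsl at 3.06 ± 0.20. In the matrix and contractile list 0 rose and 13 fell of 14 (adjusted p = 1.1e-09, adjusted p = 0.08 estimated), including Col1a1 (-3.14 ± 0.22) and Postn (-3.26 ± 0.22).

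After 7 days of caMEK1 the tumour suppressor Cdkn2a stood at 255 ± 17.1 vs 35.6 ± 6.99, log2FC 2.82 ± 0.14, adjusted p = 2.7e-12, and its neighbour Cdkn2b at 201 ± 19.3 vs 60.6 ± 15, adjusted p = 1.9e-08. The CDK inhibitor Cdkn1c, which encodes p57, rose to 84.6 ± 11.2 vs 17.4 ± 6.55. Cdkn1a, which encodes p21, was not called (188 ± 5.44 vs 170 ± 9.41, adjusted p = 0.1, or adjusted p = 0.042 with the replicate number as a block). Lamin B1, whose loss marks senescent cells, fell (Lmnb1, 11.2 ± 1.58 vs 42.2 ± 4.72, log2FC -1.82 ± 0.13, adjusted p = 2.7e-10), and Mki67 went to 4.37 ± 1.34 vs 20.7 ± 2.34. The classical secreted factor Il6 fell, at 0.699 ± 0.391 vs 5.82 ± 1.32, adjusted p = 1.3e-05, and so did the stress cytokine Gdf15 (log2FC -1.88 ± 0.21). Endogenous Map2k1 and Map2k6 rose, at 0.23 ± 0.06 and 1.31 ± 0.16.

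The largest rises at day 7 of caMEK1 were Nptx1 (329 ± 26.1 vs 1.68 ± 0.122, log2FC 6.94 ± 0.31), Mmp3 (419 ± 251 vs 2.13 ± 0.874, log2FC 6.88 ± 0.71) and Nefl (140 ± 16 vs 0.37 ± 0.0602, log2FC 6.68 ± 0.43). Sema7a (161 ± 15.1 vs 1.9 ± 0.21) and the protease Mmp10 (108 ± 20.4 vs 1.11 ± 0.24) rose too. The placental prolactin genes Prl3d2, Prl3d3 and Prl2c3 are near-identical to their neighbours, so their rises of 6.12, 5.93 and 5.65 are uncertain as to the gene. The falls were led by C1qtnf3 (-3.92), the muscle actin Actg2 (15.9 ± 5.77 vs 237 ± 39.9), Ccn5 (-3.81) and the growth factor Ccn2 (54.1 ± 30.6 vs 667 ± 31.8). Tnmd (-3.58), the innate immune protein Ptx3 (-3.57) and Lox (54.5 ± 12.2 vs 625 ± 42.7, log2FC -3.52 ± 0.12) followed. Called genes numbered 7042, with 3785 up and 3257 down.

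Of the ERK output genes at day 7 16 rose and 2 fell of 19 (adjusted p = 0.00038, adjusted p = 0.11 estimated). Dusp6 stood at 129 ± 9.31 vs 29 ± 1.66 and Spry4 at 38.1 ± 2.24 vs 7.87 ± 0.842, with Spry1, an inhibitor of the same family, lower by log2 -2.22 ± 0.15. SASP genes split, where 19 rose and 8 fell of 31 (adjusted p = 0.078, 20 and 9 adjusted over the list alone): Areg (113 ± 26.8 vs 2.01 ± 0.552) and Igfbp3 (363 ± 16.5 vs 8.86 ± 1) rose while Il6 fell. The proliferation list fell, and 1 rose and 31 fell of 33 (adjusted p = 4.4e-17, adjusted p = 0.16 estimated), Rrm2 at -2.71 ± 0.11 and Ccna2 at -2.31 ± 0.14. Lysosome genes rose without exception among those called (15 rose and 0 fell of 16, adjusted p = 1.2e-06, adjusted p = 0.16 estimated), Ctsl reaching 851 ± 133 vs 110 ± 17.4 and the cholesterol exporter Npc1 2.37 ± 0.07 on the log2 scale. The metal binding Mt1 (2.95 ± 0.12) and Mt2 (3.47 ± 0.14) rose. Down went matrix and contractile genes (0 rose and 13 fell of 14, adjusted p = 1.1e-08, adjusted p = 0.11 estimated), with Acta2 at 323 ± 146 vs 2439 ± 164.

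For CDK inhibitors at day 7 3 rose and 1 fell of 7 (adjusted p = 0.24, 3 and 0 adjusted over the list alone) and for the Notch pathway 4 rose and 2 fell of 6 (adjusted p = 0.39), with the receptor Notch2 at 2.08 ± 0.10. Epithelial markers moved in these fibroblasts: Krt18 rose to 205 ± 11.4 vs 11.7 ± 7.27 and Epcam by log2 2.70 ± 0.13 (4 rose and 2 fell of 6, adjusted p = 0.18). Cells without doxycycline were taken at day 2 only, so at days 4 and 7 time in culture and doxycycline cannot be told apart. Whether the 3 replicates were separate cultures is not stated.

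**Figure D2:**
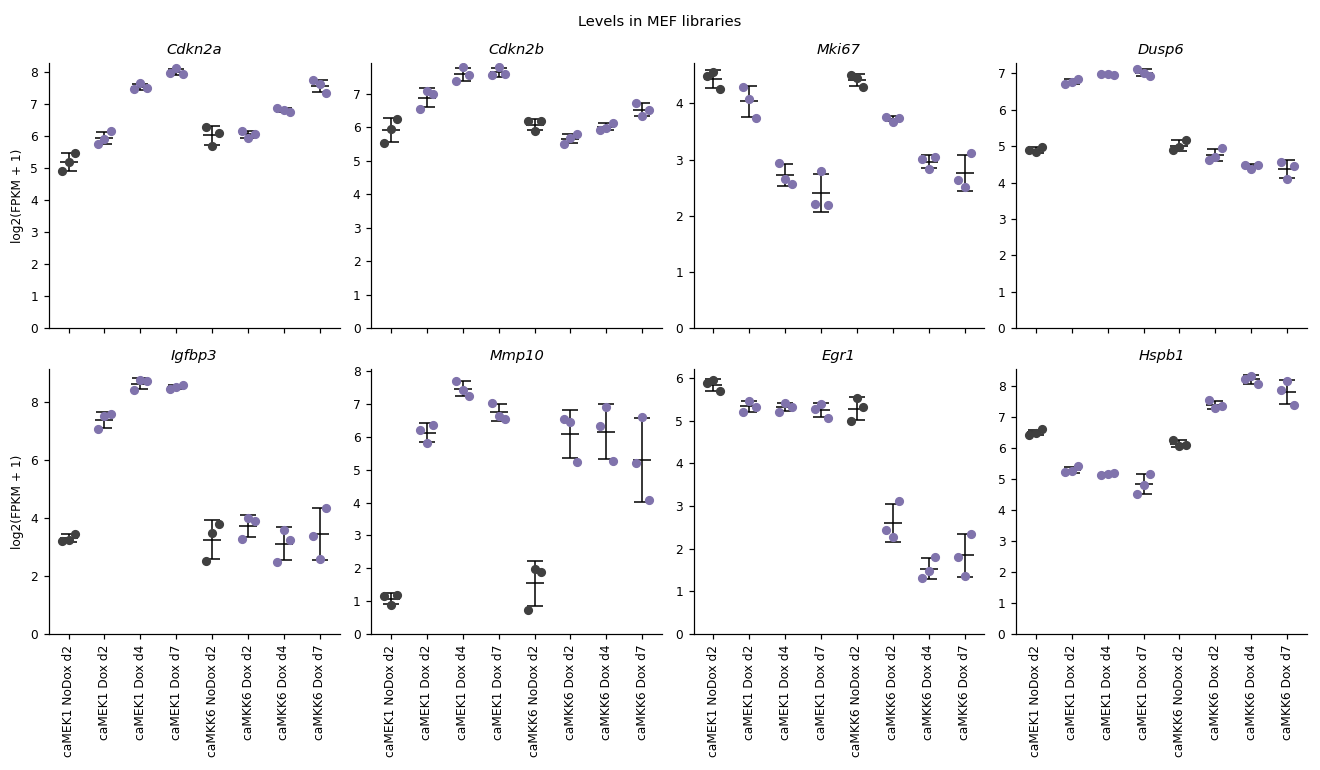
Levels in MEFs as log2(FPKM + 1) on the vertical axis, 1 point per library (grey without doxycycline, purple with), with the mean and SD of each group of 3 as black bars. Cdkn2a climbs with days of doxycycline for both kinases, Dusp6 is above the cells without doxycycline only under caMEK1, Egr1 falls furthest in caMKK6 cells, and Hspb1 rises there and falls under caMEK1.

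caMKK6 was followed in the same way (3 libraries per group). By day 2 the protease Mmp10 had gone from 2.12 ± 1.26 to 72.3 ± 31.1 FPKM (log2FC 4.54 ± 0.50, adjusted p = 2.2e-06). The mast cell protease gene Mcpt8 went from 3.5 ± 1.88 to 101 ± 58.4. Hmox1, which breaks down haem (485 ± 34.6 vs 127 ± 13.2, log2FC 1.92 ± 0.17, adjusted p = 1.9e-07), the cystine importer Slc7a11 (2.30 ± 0.17) and Gsta4 (1.87 ± 0.27) rose. Immediate early Egr1 fell furthest (5.29 ± 2.06 vs 38.3 ± 7.06, adjusted p = 1.2e-07), followed by Aspn (-2.54 ± 0.32) and the matrix protein Ltbp2 (-2.48 ± 0.58). The prolactin gene Prl2c3 (5.47 ± 0.46) is again uncertain as to the gene. Of 4443 genes called, 1625 rose and 2818 fell.

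NRF2 targets rose at day 2 of caMKK6, where 10 rose and 0 fell of 13 (adjusted p = 3.7e-08, adjusted p = 0.32 estimated, 10 and 1 adjusted over the list alone). SASP genes, with Mmp13 (2.82 ± 0.37) and Mmp12 (2.43 ± 0.29), rose too: 11 rose and 3 fell of 31 (adjusted p = 0.0047, adjusted p = 0.32 estimated). The heat shock gene Hspb1 rose (1.25 ± 0.15). Of the proliferation genes 0 rose and 9 fell of 33 (adjusted p = 0.17), Mki67 by -0.69 ± 0.17.

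At day 4 of caMKK6, Mki67 fell to 6.82 ± 0.613 vs 20.4 ± 1.64, adjusted p = 2e-06, and Cdkn1c rose by log2 3.04 ± 0.26 and Cdkn2a by 0.80 ± 0.14. Egr1 had the largest fall (-3.75 ± 0.21), then Ltbp2 (-2.82 ± 0.58) and the imprinted gene Dlk1 (-2.53 ± 0.44). The tight junction gene Cldn4 rose to 33.4 ± 6.5 vs 0.275 ± 0.0732. Prl2c3 and Prl3d2, uncertain as to the gene, rose by 5.29 and 4.81. In total 5088 genes were called, 1942 up and 3146 down. Every proliferation gene fell, as 0 rose and 33 fell of 33 (adjusted p = 2.9e-16, adjusted p = 0.31 estimated), and lysosome genes rose (11 rose and 0 fell of 16, adjusted p = 6.4e-06, adjusted p = 0.31 estimated, 12 and 0 adjusted over the list alone).

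By day 7 caMKK6 MEFs held 188 ± 24.9 vs 64.2 ± 13.2 of Cdkn2a (log2FC 1.55 ± 0.14, adjusted p = 1.4e-07), and p21's gene Cdkn1a rose (219 ± 5.49 vs 172 ± 5.37, adjusted p = 0.00099). Cdkn2b rose less (92 ± 12.6 vs 67.1 ± 7.96, adjusted p = 0.035), a call lost in 3 of 6 leave-one-out runs, with no filter (adjusted p = 0.055) and with quantile normalization (adjusted p = 0.072), and Cdkn1c stood at 74.9 ± 31 vs 10.6 ± 1.07. Lmnb1 (16.8 ± 3.27 vs 39.6 ± 3.84, adjusted p = 6.4e-07) and Mki67 (5.9 ± 1.6 vs 20.4 ± 1.64, adjusted p = 3.8e-07) fell. Gdf15 fell (-0.98 ± 0.21), and no call was made for Il6 (1.11 ± 0.447 vs 1.36 ± 0.619, adjusted p = 0.73). The ERK targets Dusp6 (20 ± 3.37 vs 31.5 ± 3.48, adjusted p = 6.1e-05) and Spry4 (-0.56 ± 0.11) fell. Map2k1 rose (0.21 ± 0.06) and endogenous Map2k6 was not called (log2FC -0.12 ± 0.16, adjusted p = 0.58).

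Cldn4 (24.9 ± 9.11 vs 0.275 ± 0.0732, log2FC 4.28 ± 0.32), Mmp10 (49.4 ± 41.9 vs 2.12 ± 1.26, log2FC 3.75 ± 0.50), the microtubule gene Stmn4 (18.9 ± 11.2 vs 0.5 ± 0.491), the steroid enzyme gene Hsd3b6 (3.52 ± 0.71, not called by voom) and the protease Mmp12 (21.9 ± 10.6 vs 1.09 ± 0.658) rose at day 7 of caMKK6. Prl2c3, Prl2c2 and Prl3d2, at 5.12, 3.94 and 3.60, are uncertain as to the gene. Egr1 fell most (2.72 ± 1.28 vs 38.3 ± 7.06, log2FC -3.44 ± 0.21). Nid2, Ltbp2, Slc1a6, Dlk1, Fos, Lgals9 and Ier2 followed at -2.18, -2.17, -2.17, -2.04, -1.98, -1.97 and -1.93. The count was 4629, with 1904 rises and 2725 falls.

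Proliferation genes fell at day 7 of caMKK6 (0 rose and 32 fell of 33, adjusted p = 3.4e-23, adjusted p = 0.12 estimated). Lysosome genes rose (15 rose and 0 fell of 16, adjusted p = 2.1e-10, adjusted p = 0.084 estimated), Gpnmb by 1.62 ± 0.22 and Ctsb by 1.44 ± 0.08. The fall of the immediate early list held with an estimated correlation too (2 rose and 14 fell of 16, adjusted p = 1.1e-05, adjusted p = 0.049 estimated), Atf3 being a member that rose (1.68 ± 0.16). ERK output genes were down, as 2 rose and 12 fell of 19 (adjusted p = 0.0019, adjusted p = 0.084 estimated), among them Ccnd1 (-1.28 ± 0.28) and Fosl1 (-1.18 ± 0.08). SASP genes split evenly (7 rose and 8 fell of 31, adjusted p = 0.79, 7 and 9 adjusted over the list alone), with Mmp13 (2.90 ± 0.37) and Igfbp5 (361 ± 189 vs 75.9 ± 35.9) among the rises. The small heat shock gene Hspb1 stood at 231 ± 60.4 vs 70.4 ± 5.82. Under median scaling the share of rises went from 36.6% to 54% at day 2 (2317 up, 1976 down), from 38.2% to 54.9% at day 4 (2726 up, 2241 down) and from 41.1% to 51.9% at day 7 (2362 up, 2189 down). Quantile normalization gave 48.9% at day 2 (1963 up, 2048 down). In 5 of the 12 caMKK6 libraries the MEK1 transgene was listed above 5 FPKM, and without them the counts were 1484, 2388 and 2674. With these fewer libraries calls were lost for Ltbp2 (-2.53, -1.95 and -1.90), Mki67 at day 2 (-0.75), Cdkn2a at day 4 (0.53 ± 0.20), Dlk1 at days 4 and 7 (-1.80 and -1.47), and Cdkn2b (0.35 ± 0.25), Map2k1 (0.16) and Spry4 (-0.39) at day 7.

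The day 7 changes of the kinases were compared by subtraction (12 libraries). The neuronal genes Nptx1 (difference in log2 fold change 7.56 ± 0.43) and Nefl (7.38 ± 0.61), and Sema7a (6.24 ± 0.50), rose more under caMEK1. The actin-associated Cnn1 (-4.27 ± 0.29) and Acta1 (-4.11 ± 0.57) went the other way, as did the chemokine gene Cxcl14 (-4.35 ± 0.41). The rise of Cdkn2a was larger under caMEK1 by 1.27 ± 0.20 (adjusted p = 5.6e-05) and that of Cdkn2b by 1.29 ± 0.23 (adjusted p = 0.00019). No difference was called for Cdkn1a (-0.21 ± 0.11, adjusted p = 0.13) or Mki67 (-0.38 ± 0.24, adjusted p = 0.22). Lmnb1 (-0.62 ± 0.18, adjusted p = 0.01) and Il6 (-1.87 ± 0.44, adjusted p = 0.0023) were lower under caMEK1. The changes differed for 4287 genes, 2639 higher and 1648 lower under caMEK1.

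ERK output was among the groups that differed between the kinases, higher in caMEK1 for 16 of 19 genes and lower for 1 (adjusted p = 2.7e-08, adjusted p = 0.0046 estimated), with Dusp6 at 2.76 ± 0.14 and Dusp5 at 2.91 ± 0.17. Matrix and contractile genes were lower in 13 of 14 (adjusted p = 2.3e-13, adjusted p = 0.022 estimated, 0 and 14 adjusted over the list alone), Postn by -3.41 ± 0.31. Heat shock genes were lower for 4 of 10 (adjusted p = 0.0028, adjusted p = 0.2 estimated) with Hspb1 at -3.33 ± 0.22. The separate comparisons share no library but share doxycycline and time, so common changes need not come from a kinase. Rises in both numbered 1196 (635.1 by chance), falls 1686 (782.2) and opposite moves 446 (1455.5). Median scaling moved the typical gene by 0.12 log2 and turned the split to 1863 up and 2396 down, and quantile normalization to 2083 up and 2178 down.

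In liver, mCherry cells of caMEK1 mice (n = 3) were compared with mCherry cells of control mice on doxycycline (n = 2). Afp, which encodes the fetal serum protein alpha-fetoprotein, stood at 704 ± 452 vs 0.301 ± 0.0825, log2FC 8.74 ± 0.62, adjusted p = 2.5e-08. The heparan sulfate protein Gpc3 stood at 77.6 ± 41.8 vs 0.0302 ± 0.00027 and the prohormone processing enzyme Cpe at 150 ± 120 vs 0.0309 ± 0.0437. The fatty acid elongase Elovl3 fell (0.233 ± 0.0921 vs 314 ± 11.7, log2FC -8.00 ± 0.31, adjusted p = 8.6e-12). The carbonic anhydrase Car3 (0.649 ± 0.262 vs 643 ± 108) and Cyp7b1, an enzyme of oxysterol and bile acid metabolism (1.97 ± 0.717 vs 377 ± 78.6), fell with it. Cdkn2b rose to 10.4 ± 7.52 vs 0.0877 ± 0.0421, log2FC 3.20 ± 0.31, adjusted p = 9.7e-07. Cdkn1a was called (39 ± 26.4 vs 7.97 ± 0.717, adjusted p = 0.046), but the call was lost in 4 of 5 leave-one-out runs, and with voom, no filter or a pseudocount of 0.1.

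Other large rises under caMEK1 in liver mCherry cells were Sult1e1, which inactivates oestrogens (154 ± 77.7 vs 0.131 ± 0.00117, log2FC 6.94 ± 0.33), Ly6d (240 ± 84 vs 1.46 ± 1.91, log2FC 6.80 ± 0.54) and Cxcl17 (6.46 ± 0.56). The secreted peptide gene Tff3 (218 ± 28.9 vs 1.97 ± 0.215) rose too. Cyp4a12a (0.205 ± 0.141 vs 329 ± 11.3), Hsd3b5 (0.212 ± 0.189 vs 133 ± 15.3) and Ces1f (-6.68 ± 1.16) were among the largest falls. So were the pheromone carriers Mup17 and Mup9 (-8.79 and -8.48), of a near-identical family, so that the gene is uncertain. No call was made for Lmnb1 (0.683 ± 0.0463 vs 1.02 ± 0.552, adjusted p = 0.42, or adjusted p = 0.011 against untreated GFP cells), nor for Mki67, Gdf15, Map2k1 or Map2k6 (log2FC -0.85 to 0.45, adjusted p = 0.28 to 0.88). Cdkn2a and Il6 were below the level needed for a test. The count was 2806 genes, 1112 up and 1694 down.

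ERK output genes rose in these cells, as 10 rose and 1 fell of 16 (adjusted p = 3.1e-06, adjusted p = 0.34 estimated, 12 and 1 adjusted over the list alone). Dusp5 went to 30.9 ± 13.8 vs 0.443 ± 0.0656 and the growth factor Hbegf up by 3.07 ± 0.23, while Myc fell (-3.05 ± 0.65, or -0.96 ± 0.58 and not called against untreated GFP cells of caMEK1 mice). Dusp6 was at 49.2 ± 0.141 vs 12.1 ± 2.84, a call lost in 5 of 5 runs, with voom, no filter and without animal 3, and Spry4 at 7.67 ± 2.81 vs 2.02 ± 0.525. For p53 targets 9 rose and 1 fell of 18 (adjusted p = 0.0041, adjusted p = 0.4 estimated, 10 and 1 adjusted over the list alone), Phlda3 by 1.75 ± 0.37. For the integrated stress response 4 rose and 1 fell of 12 (adjusted p = 0.023, adjusted p = 0.4 estimated, 5 and 1 adjusted over the list alone), with the amino acid enzymes Psat1 (4.19 ± 0.36) and Asns (3.23 ± 0.46). Hepatocyte genes fell, where 2 rose and 13 fell of 23 (adjusted p = 0.00042, adjusted p = 0.37 estimated, 2 and 14 adjusted over the list alone), with Cyp8b1, which shapes the bile acid pool, at -5.73 ± 0.96 and G6pc, the last step of glucose release, at -4.00 ± 0.68.

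Among secreted factors in caMEK1 mCherry hepatocytes Igfbp3 (4.16 ± 0.79) and Mmp9 (2.44 ± 0.48) rose (Mmp9, like Mup9, not by voom), and for the SASP list 6 rose and 2 fell of 20 (adjusted p = 0.1). The acute phase list was mixed (5 rose and 4 fell of 25, adjusted p = 0.81, 6 and 5 adjusted over the list alone), its median at -0.26 while the test pointed up. The iron binding Lcn2 stood at 445 ± 334 vs 14.3 ± 0.659 and the iron hormone Hamp at 100 ± 68.4 vs 668 ± 56.3. The erythroid marker Alas2 was lower (-4.78 ± 0.38). Quantile normalization gave 1490 up and 1484 down, and leaving out control mCherry replicate 1 or 2 left 1426 or 1412 calls, the lone control then being assumed to vary like the other groups. Both control mCherry libraries, and both libraries of caMEK1 animal 3, had less than 0.5 FPKM of all 4 Y-linked genes examined.

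For caMKK6, 2 mCherry libraries were compared with 2 of control mice. Gstm3, a glutathione transferase, reached 773 ± 392 vs 5.46 ± 2.97, log2FC 6.89 ± 0.72, adjusted p = 6.1e-06. Cyp2b10, a drug-metabolising enzyme, reached 115 ± 121 vs 0.595 ± 0.13, adjusted p = 6.2e-05, and Cyp3a11, of the same kind, 3435 ± 2058 vs 89.9 ± 27.5. Against untreated GFP cells of caMKK6 mice Cyp3a11 (log2FC 1.56 ± 0.71) and Mup9 (-4.23 ± 1.85) were not called. The leptin receptor Lepr (100 ± 94.1 vs 0.299 ± 0.0299), the Wnt ligand Wnt4 (49.9 ± 35.2 vs 0.0388 ± 0.0277), the steroid enzyme Cyp17a1 (90.3 ± 20.2 vs 1.66 ± 0.0888) and the endotoxin receptor Cd14 (log2FC 5.08 ± 0.94) rose with them. Elovl3 (0.111 ± 0.0997 vs 314 ± 11.7, adjusted p = 3e-11) and Car3 (7.44 ± 10.5 vs 643 ± 108) fell, and so did Mup17, Mup9, Mup16, Mup11, Mup18 and Mup7 at -9.95, -9.45, -8.06, -7.79, -7.48 and -6.95, uncertain as to the gene. Cyp2a4 (5.30 ± 1.55, lost in 4 of 4 runs) has a near-identical neighbour too, and Mup7 was lost in 2 of 4 and Mup9 by voom.

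Of the senescence genes in caMKK6 mCherry hepatocytes, Cdkn1a (32.3 ± 14.2 vs 7.97 ± 0.717, adjusted p = 0.061) and Cdkn2b (0.0572 ± 0.0809 vs 0.0877 ± 0.0421, adjusted p = 0.95) were not called. Cdkn1a was called with animal as a block (1.83 ± 0.71, adjusted p = 0.049) and against untreated GFP cells (2.96 ± 0.68, adjusted p = 0.0035). Nor were Lmnb1, Mki67, Gdf15, Dusp6, Spry4 and Map2k6 (log2FC -0.45 to 0.50, adjusted p = 0.33 to 1). Endogenous Map2k1 rose by 1.00 ± 0.18. Called genes numbered 3958, 2995 up and 963 down.

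Interferon genes fell in caMKK6 mCherry hepatocytes (0 rose and 10 fell of 20, adjusted p = 6.5e-07, adjusted p = 0.87 estimated, 0 and 11 adjusted over the list alone), Bst2 by -2.33 ± 0.51 and Rsad2 by -1.57 ± 0.26. Hepatocyte genes were mostly down (3 rose and 11 fell of 23, adjusted p = 0.0002, adjusted p = 0.74 estimated, 5 and 12 adjusted over the list alone), with Cyp2e1 at -3.37 ± 0.56 and the transporter Slco1b2 at -3.95 ± 0.70. In the stress response list, with Asns (4.12 ± 0.51) and Trib3 (3.32 ± 0.65), 7 rose and 0 fell of 12 (adjusted p = 0.071, 8 and 0 adjusted over the list alone). Of the NRF2 targets, with Srxn1 (2.91 ± 0.37) and Nqo1 (2.05 ± 0.41), 6 rose and 1 fell of 13 (adjusted p = 0.5). Cdt1, Mcm6 and Pcna, which act in DNA replication, rose by 1.42, 1.20 and 1.05, Pcna being at 0.47 ± 0.19 and not called against untreated GFP cells. The median of all genes moved by 0.33 log2, and scaling it away left 1196 up and 1921 down, quantile normalization 1441 and 1390. Without control mCherry replicate 1 or 2, or caMKK6 mCherry replicate 1, the counts were 2423, 1662 and 2228.

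In the GFP cells around them, caMEK1 mice on doxycycline (n = 3) were compared with caMEK1 mice without it (n = 3). Acute phase genes rose in the surrounding hepatocytes: Lcn2 went to 732 ± 508 vs 1.54 ± 0.486, log2FC 7.93 ± 0.54, adjusted p = 3.6e-08. The serum amyloid genes Saa2 and Saa1 went to 380 ± 346 vs 4.5 ± 1.71 and 610 ± 534 vs 13.6 ± 2.16. The metal binding Mt2 rose (858 ± 412 vs 11.3 ± 16, adjusted p = 0.00015), and so did Mt1 (5.70 ± 0.94). Afp (42 ± 43.3 vs 0.17 ± 0.0568) and Sult1e1 (5.25 ± 0.30) were up here as well. Carried-over RNA may add to Afp: the mCherry reporter was at 0% to 10.98% and the MEK1 transgene at 0.94% to 4.28% of mCherry-cell levels. Car3 (2.12 ± 1.35 vs 1166 ± 240), Elovl3 (-8.00 ± 0.28), Cyp4a12a (-7.01 ± 0.48), Hsd3b5 (-6.87 ± 0.18) and the peroxisomal thiolase Acaa1b (-6.55 ± 0.76) fell furthest, with Ces1f, Sult2a8 and Mup17 at -6.25, -6.11 and -5.99. Cdkn1a was called (20.2 ± 11.7 vs 5.08 ± 3.75, adjusted p = 0.019, lost in 3 of 6 runs), Map2k1 fell (-0.63 ± 0.15), and Cdkn2b, Lmnb1, Mki67, Gdf15, Dusp6, Spry4 and Map2k6 were not called (log2FC -0.80 to 0.70, adjusted p = 0.064 to 0.65). Lmnb1 was called lower without animal 3 (-0.62 ± 0.18) and with quantile normalization (-0.44 ± 0.15), which lost Map2k1 (-0.22 ± 0.13), and Spry4 higher with median scaling and quantile normalization (0.93 and 1.00). Of 3989 genes called, 670 rose and 3319 fell.

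Of the acute phase genes 21 rose and 0 fell of 25 (adjusted p = 1e-22, adjusted p = 0.041 estimated, 21 and 1 adjusted over the list alone), a call that held both ways. For immediate early genes, with Egr1 at 2.78 ± 0.74 and Junb at 2.69 ± 0.55, 8 rose and 0 fell of 14 (adjusted p = 4e-07, adjusted p = 0.12 estimated, 9 and 0 adjusted over the list alone). For SASP genes, the chemokine Cxcl1 (3.17 ± 0.65) among them, 6 rose and 1 fell of 20 (adjusted p = 1.7e-06, adjusted p = 0.12 estimated). By the list test markers of other cell types stood higher relative to the other genes, while the median of all genes fell. There were macrophage genes (4 rose and 0 fell of 12, adjusted p = 1.7e-06, adjusted p = 0.25 estimated, 1 and 0 adjusted over the list alone), with Marco at 12.8 ± 4.87 vs 0.689 ± 0.363, and endothelial genes (2 rose and 0 fell of 8, adjusted p = 0.00032, adjusted p = 0.28 estimated), with Pecam1 at 1.65 ± 0.45 (1.10 ± 0.43 and not called without animal 3). There were also neutrophil genes (3 rose and 0 fell of 3, adjusted p = 2.1e-05, adjusted p = 0.12 estimated) and stromal genes (1 rose and 0 fell of 8, adjusted p = 0.00033, adjusted p = 0.28 estimated). Against GFP cells of control mice on doxycycline, Saa1, Saa2, Mt1, Mt2, Egr1, Junb, Pecam1 and Cdkn1a (0.66 ± 0.68) were not called (log2FC 0.64 to 2.49), Marco was at 1.40 ± 0.49 and Cxcl1 at -0.82 ± 0.73. The median of all genes moved by -0.23 log2, and median scaling gave 1291 up and 1801 down, quantile normalization 1071 and 1391.

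GFP cells of caMKK6 mice were compared likewise (2 with doxycycline, 3 without). Saa2 rose to 1870 ± 278 vs 77.8 ± 118, log2FC 6.03 ± 1.15, adjusted p = 0.0029, Lcn2 to 391 ± 56.4 vs 3.47 ± 3.51, adjusted p = 1.8e-06 and the plasma protein gene Orm2 to 769 ± 78.2 vs 33.8 ± 30.7. Mt2 (6.13 ± 1.18), Mt1 (5.10 ± 1.06), Isyna1 (72.9 ± 19.6 vs 1.25 ± 0.284), Saa1 (4.65 ± 1.08) and the growth factor binding Igfbp1 (4.55 ± 0.89) rose as well. Car3 (-8.64 ± 0.80), Elovl3 (-7.68 ± 0.31), Hsd3b5 (-7.24 ± 0.20), Selenbp2 (-6.68 ± 0.88) and Cyp4a12a (-6.24 ± 0.54) fell, with Mup17, Mup21 and Mup11 at -7.95, -6.88 and -6.73. Cdkn1a (8.62 ± 2.4 vs 3.21 ± 1.21, adjusted p = 0.21), Cdkn2b, Lmnb1, Mki67, Gdf15, Dusp6, Spry4, Map2k1 and Map2k6 were not called (log2FC -0.60 to 0.30, adjusted p = 0.16 to 0.98 for these last 8). There were 1974 calls, 540 up and 1434 down.

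For acute phase genes in caMKK6 GFP cells 20 rose and 0 fell of 25 (adjusted p = 1.8e-20, adjusted p = 0.06 estimated, 22 and 0 adjusted over the list alone). The stress response (5 rose and 1 fell of 12, adjusted p = 0.006, adjusted p = 0.53 estimated, 7 and 1 adjusted over the list alone) was up, Ddit4 by 4.25 ± 0.84. Immediate early genes were up (4 rose and 0 fell of 14, adjusted p = 0.0034, adjusted p = 0.53 estimated, 7 and 0 adjusted over the list alone), Klf6 by 3.02 ± 0.59. Endothelial markers were up (1 rose and 0 fell of 8, adjusted p = 0.0045, adjusted p = 0.53 estimated, 3 and 0 adjusted over the list alone). So were macrophage markers (1 rose and 0 fell of 12, adjusted p = 0.0052, adjusted p = 0.61 estimated, 0 and 0 adjusted over the list alone). Against control GFP cells on doxycycline, Saa1, Mt1, Mt2, Igfbp1 and Ddit4 were not called (log2FC 1.61 to 3.32), and Map2k1 was called lower (-0.76 ± 0.18). Which library was left out decided the count: 206 without doxycycline GFP replicate 1, 3950 without replicate 2, and 1004 and 1122 without untreated replicates 1 and 2. Median scaling gave 813 up and 1239 down, quantile normalization 667 and 909.

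GFP cells of control mice were compared with and without doxycycline (2 with, 3 without). These groups differ in Y-linked reads as well, Ddx3y being at 0.0611 and 0.0633 FPKM with doxycycline and at 13.1 to 13.7 without. The signalling adaptor Tifa rose (6.81 ± 1.13 vs 1.57 ± 0.103, adjusted p = 0.023), and the glycogen regulator Ppp1r3c (4.9 ± 0.499 vs 35.6 ± 6.94, adjusted p = 0.038) and Cyp3a59 (5.24 ± 1.02 vs 26.9 ± 13, adjusted p = 0.031) fell. Each call was lost in 5 of 5 leave-one-out runs and with quantile normalization. Only 9 genes were called (5 up, 4 down), and 447 had an unadjusted p below 0.05. No acute phase gene was called over all genes, but the list stood higher with a median of 0.96 (adjusted p = 2.2e-18, adjusted p = 0.089 estimated, 11 and 0 adjusted over the list alone). The test of macrophage genes pointed up too (adjusted p = 7.5e-07, adjusted p = 0.62 estimated, 1 and 0 adjusted over the list alone). Voom called 2 genes, quantile normalization 5 and no filter 15, and without a library the count was 0 (doxycycline replicates 1 and 2, untreated replicate 1), 3 (untreated replicate 2) or 2 (untreated replicate 3).

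**Figure D3:**
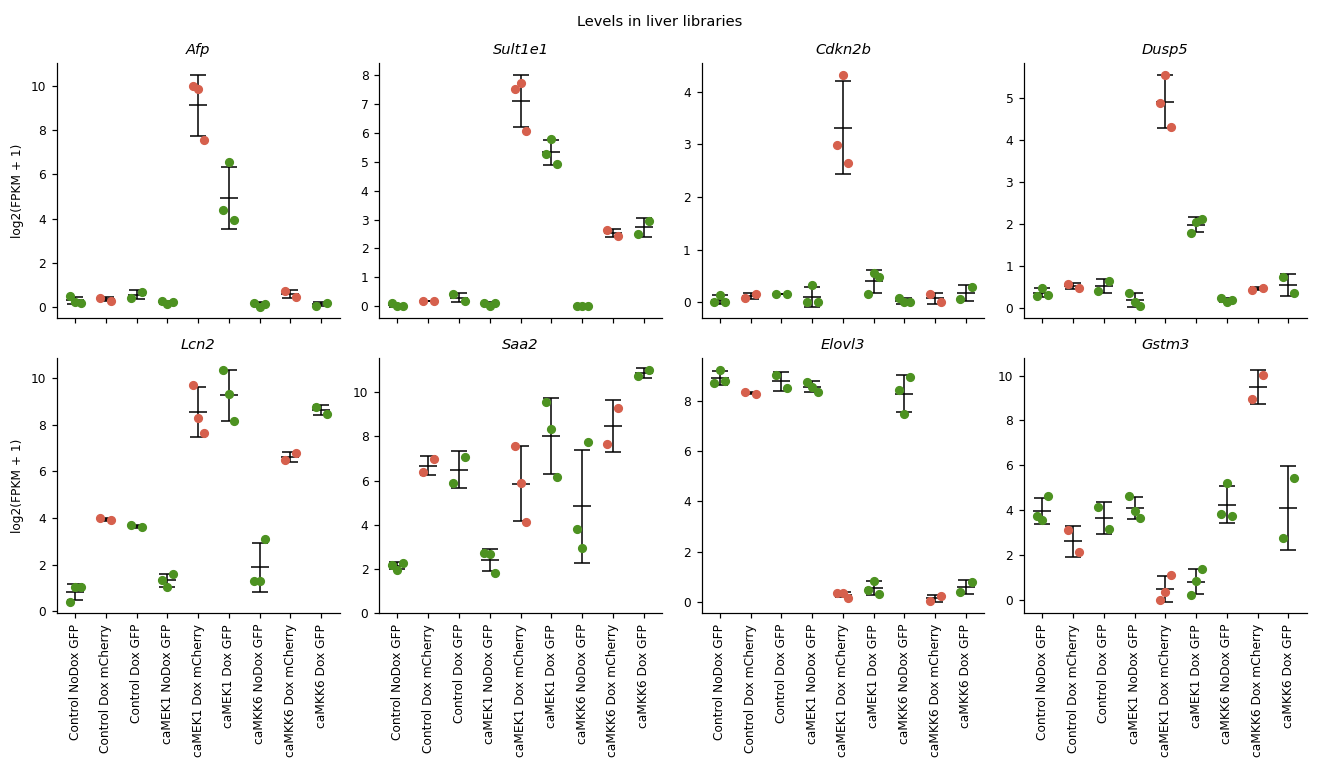
Levels in liver as log2(FPKM + 1) on the vertical axis, 1 point per library (red mCherry, green GFP), with the mean and SD of each group of 2 or 3 as black bars. Afp, Cdkn2b and Dusp5 are highest in caMEK1 mCherry cells, Gstm3 in caMKK6 mCherry cells, and Lcn2 is higher on doxycycline in all genotypes, least in control mice.

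Between the colours of the same caMEK1 mice on doxycycline (n = 3 and 3), mCherry cells held more Ly6d (240 ± 84 vs 12.2 ± 5.92), Afp (704 ± 452 vs 42 ± 43.3, adjusted p = 0.00014) and Cpe (150 ± 120 vs 7.8 ± 9.03). They held more Cdkn2b (10.4 ± 7.52 vs 0.328 ± 0.19, adjusted p = 3.5e-06) and Dusp5 (30.9 ± 13.8 vs 2.98 ± 0.483). Marco, a macrophage receptor, was lower (1.32 ± 0.897 vs 12.8 ± 4.87), as were Prg2 (-2.23 ± 0.55, not by voom) and the chemokine Cxcl13 (-2.05 ± 0.34). ERK output genes were higher (6 rose and 0 fell of 16, adjusted p = 7.9e-07, adjusted p = 0.14 estimated, 9 and 0 adjusted over the list alone). Acute phase genes were lower (0 rose and 6 fell of 25, adjusted p = 2.9e-11, adjusted p = 0.14 estimated, 0 and 7 adjusted over the list alone), with Hpx at 3946 ± 850 vs 10291 ± 3678 (not called with no filter). Macrophage markers were lower (0 rose and 1 fell of 12, adjusted p = 6e-09, adjusted p = 0.33 estimated, 0 and 9 adjusted over the list alone). The count of 488 (389 up, 99 down) became 1277 with animal as a block, and median scaling gave 279 up and 136 down. Without mCherry replicates 1, 2 and 3 it was 307, 193 and 809, and without GFP replicate 2 it was 312.

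In caMKK6 mice (n = 2 and 2) Gstm3 (773 ± 392 vs 23.8 ± 25.4, adjusted p = 0.00037), Cyp2a5 (1216 ± 354 vs 46.2 ± 41.2) and the transcription factor Fezf1 (37.6 ± 27.8 vs 0.284 ± 0.0829, adjusted p = 5.1e-08) were higher in mCherry than in GFP cells. Cyp2e1 (-2.16 ± 0.56), Isyna1 (-2.06 ± 0.54) and Nnmt (-1.91 ± 0.46) were lower, calls lost in 4 of 4, 4 of 4 and 2 of 4 runs and with quantile normalization, the first pair with no filter and Isyna1 with voom too. Acute phase genes were lower (0 rose and 2 fell of 25, adjusted p = 7.3e-15, adjusted p = 0.18 estimated, 0 and 4 adjusted over the list alone), with Itih4 at 1212 ± 342 vs 3615 ± 46.1. The test put macrophage genes lower with none called (adjusted p = 1.7e-05, adjusted p = 0.53 estimated). Of 444 calls 414 were up and 30 down. The median gene moved by 0.25 log2, median scaling left 127 up and 57 down, quantile normalization 156 and 43, and animal as a block gave 954. Leaving out GFP replicate 1 gave 1478 and leaving out mCherry replicates 1 and 2 gave 724 and 261.

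In control mice (n = 2 and 2) the colours differed in 11 genes, among them Cdc42, which organises actin (15.8 ± 0.129 vs 42.2 ± 1.45, adjusted p = 0.026), Camk2n1 (-1.29 ± 0.23) and Krcc1 (-1.17 ± 0.21). These were lower in mCherry cells, each lost in 4 of 4 runs and with median scaling, quantile normalization and the block. Macrophage genes stood lower (adjusted p = 0.005, adjusted p = 0.89 estimated) and acute phase genes higher (adjusted p = 4.7e-08, adjusted p = 0.59 estimated) by the list test, with none called. The median gene moved by -0.27 log2, and 72.1% of tested genes separated completely (33.3% by chance), so few calls need not mean like colours. Voom called 6 genes, median scaling 4, quantile normalization 3, no filter 50 and animal as a block 6, and without a library the count was 0 or 2.

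Set directly against each other, caMEK1 (n = 3) and caMKK6 (n = 2) mCherry hepatocytes differed in Afp (704 ± 452 vs 0.53 ± 0.186, adjusted p = 4.7e-08), Ly6d (7.03 ± 0.54) and Cpe (6.77 ± 0.63), higher with caMEK1. Gstm3 (0.479 ± 0.598 vs 773 ± 392, adjusted p = 4.7e-08), Cyp3a11 (-6.21 ± 0.71) and Cyp2b10 (-5.35 ± 0.69) were higher with caMKK6. Cdkn2b (10.4 ± 7.52 vs 0.0572 ± 0.0809, log2FC 3.24 ± 0.31, adjusted p = 1.1e-06) and Dusp6 (49.2 ± 0.141 vs 13.8 ± 16, adjusted p = 0.011) were higher with caMEK1. No difference was called for Cdkn1a (0.08 ± 0.68, adjusted p = 0.94). ERK output genes were higher with caMEK1 (7 rose and 2 fell of 16, adjusted p = 1e-07, adjusted p = 0.15 estimated, 9 and 2 adjusted over the list alone), as were SASP genes (7 rose and 1 fell of 20, adjusted p = 2.2e-05, adjusted p = 0.15 estimated, 8 and 1 adjusted over the list alone). So were sterol genes (9 rose and 1 fell of 19, adjusted p = 2.1e-06, adjusted p = 0.33 estimated), Sqle by 2.99 ± 0.71 and Hmgcs1 by 2.63 ± 0.65. The count was 3292, 469 up and 2823 down, against a median shift of -0.35 log2. Median scaling gave 972 up and 837 down (1809), quantile normalization 845 and 897 (1742), and without caMEK1 replicate 1 there were 2090.

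The mCherry and GFP comparisons within a genotype share no library, but both colours on doxycycline came from the same animals, which the chance number leaves out. In caMEK1 livers 312 genes rose in both where 71.8 would by chance and 1298 fell in both where 542.1 would. In caMKK6 livers the numbers were 321 against 155.9 and 600 against 133.2.

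In sorted colon epithelium, mCherry cells of caMEK1 mice (n = 2) were first compared with those of control mice (n = 2). Psca, a membrane protein of stratified epithelia, went to 205 ± 8.8 vs 0.469 ± 0.409, log2FC 7.16 ± 0.33, adjusted p = 8.6e-11. The cornified envelope gene Sprr1a went to 398 ± 254 vs 4.49 ± 3.65. Sprr2h, Prss22 and Msln, listed at 0 in the controls, reached 87.4 ± 25.2, 76.3 ± 24 and 74.5 ± 51.6 FPKM. The lipase gene Pnliprp2 reached 119 ± 14.1 vs 0.754 ± 0.114. The goblet cell mucin Muc2 fell to 189 ± 5.14 vs 1501 ± 1257, adjusted p = 0.0069 (lost in 2 of 4 runs). Atoh1, the factor that specifies secretory cells, fell too (-3.05 ± 0.46). Cdkn1a rose (172 ± 52.6 vs 45.7 ± 8.98, log2FC 1.87 ± 0.45, adjusted p = 0.0068, lost in 2 of 4 runs), as did Cdkn1c (1.84 ± 0.42).

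Ly6g (799 ± 298 vs 4.88 ± 4.35) and Ly6m (6.40 ± 1.00) belong to a family of close relatives and are uncertain as to the gene. Sval1 (5.47 ± 4.6 vs 130 ± 69.6), Ccn3 (-4.20 ± 0.56), the chemokine Ccl6 (-4.06 ± 0.52), Klk1 (43.9 ± 20.9 vs 587 ± 236), Slc6a14 (-3.40 ± 0.41), Ugt2b5, the manganese exporter Slc30a10 and Fndc5 (-3.40, -3.38 and -3.33) fell furthest. Endogenous Map2k6 fell (3.79 ± 1.39 vs 7.55 ± 0.916, adjusted p = 0.045, or adjusted p = 0.072 with animal as a block, lost in 3 of 4 runs and under every alternative except the other comparator). Cdkn2b, Lmnb1, Mki67, Gdf15 and Map2k1 were not called (log2FC -0.43 to 0.29, adjusted p = 0.54 to 0.76), and Cdkn2a and Il6 were too low to test. In all 2484 genes were called, 1101 up and 1383 down.

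ERK output genes rose in caMEK1 colon cells (9 rose and 0 fell of 18, adjusted p = 8.7e-08, adjusted p = 0.077 estimated, 10 and 0 adjusted over the list alone). Spry4 went to 15.1 ± 3.34 vs 1.47 ± 0.245, Dusp6 to 89.9 ± 31.7 vs 28.3 ± 17.8 (lost in 2 of 4 runs), Dusp5 by 3.12 ± 0.43 and Epha2 by 3.42 ± 0.56. Secreted and protease-receptor genes rose with them (8 rose and 0 fell of 15, adjusted p = 8.7e-06, adjusted p = 0.084 estimated), the urokinase receptor Plaur to 61.4 ± 28.8 vs 3.12 ± 0.783 and the vessel growth factor Vegfa by 2.48 ± 0.35. The fetal-like epithelium list was up (5 rose and 0 fell of 10, adjusted p = 4.3e-05, adjusted p = 0.24 estimated), with Ly6a at 385 ± 56.7 vs 26.3 ± 4.21 and Anxa1 at 3.29 ± 0.53. Goblet genes fell (0 rose and 8 fell of 12, adjusted p = 0.0045, adjusted p = 0.47 estimated, 1 and 9 adjusted over the list alone). Stem and Wnt genes fell (0 rose and 7 fell of 15, adjusted p = 0.0016, adjusted p = 0.47 estimated, 1 and 11 adjusted over the list alone), Ascl2 by -2.54 ± 0.62 (lost in 2 of 4 runs and by voom) and Lgr5 by -1.64 ± 0.34. Krt7 (3.49 ± 0.43), Krt18 (2.97 ± 0.25) and Krt20 (2.72 ± 0.73, lost in 2 of 4 runs), keratins of simple epithelium, rose. The median gene moved by -0.12 log2 and median scaling gave 1337 up and 1009 down. Without control replicate 2 there were 1387 calls and without caMEK1 replicate 2 there were 808, and the caMEK1 libraries held fewer reads (8066418 and 8203222) than the controls (12277329 and 12957014).

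With caMKK6 (n = 3, against the same 2 controls) Wfdc18 rose most, to 204 ± 82.6 FPKM (log2FC 5.74 ± 0.56, adjusted p = 2.8e-06). The protease inhibitor Slpi rose to 61.8 ± 28.5 vs 0.445 ± 0.444 (not by voom) and the chitinase Chit1 to 46 ± 34.8 vs 0.268 ± 0.319. The trefoil peptide Tff1 went to 43.9 ± 36.3 FPKM from a control level of 0 and the matrix protease Mmp7 to 62.4 ± 33.2 vs 1.58 ± 1.04. Creatine kinase Ckb rose too (71.1 ± 40.5 vs 1.66 ± 0.401), as did Ly6d and Ang4 (4.60 ± 0.59 and 4.93 ± 1.40, families of close relatives). The immediate early gene Egr1 fell (44.9 ± 2.35 vs 301 ± 166, adjusted p = 0.00023). The largest falls were Sult1c2 (3.14 ± 2.84 vs 40.7 ± 0.91), Fndc5, Ces1d, Tppp and Fosb (-3.24, -3.22, -3.21 and -2.92), beside Gsdmc2, Gsdmc3 and Gsdmc4, which are near-identical. Cdkn1a was not called (44.8 ± 11.9 vs 45.7 ± 8.98, adjusted p = 0.95). Cdkn1c rose (19.1 ± 4.3 vs 3.88 ± 2.33, adjusted p = 0.0011). Gdf15 rose (29.7 ± 9.35 vs 12.1 ± 7.48, adjusted p = 0.049, or adjusted p = 0.051 with the block, lost in 3 of 5 runs) and Map2k6 fell (1.93 ± 1.1 vs 7.55 ± 0.916). Cdkn2b, Lmnb1, Mki67, Dusp6, Spry4 and Map2k1 were not called (log2FC -1.04 to 0.13, adjusted p = 0.19 to 0.87). Against untreated GFP cells of caMKK6 mice Mki67 was called lower (-1.52 ± 0.49), and Gdf15 (0.75 ± 0.41) and Ang4 (2.53 ± 1.25) were not called.

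Of the NRF2 targets in caMKK6 colon cells 10 rose and 0 fell of 13 (adjusted p = 4e-06, adjusted p = 0.21 estimated, 10 and 1 adjusted over the list alone), Nqo1 by 1.58 ± 0.41 and Gsta4 by 2.04 ± 0.33. Immediate early genes fell (0 rose and 7 fell of 15, adjusted p = 4.7e-05, adjusted p = 0.56 estimated, 0 and 10 adjusted over the list alone). The stress response rose (7 rose and 0 fell of 15, adjusted p = 0.0022, adjusted p = 0.21 estimated, 10 and 0 adjusted over the list alone), Slc7a11 by 2.45 ± 0.28. SASP genes rose (6 rose and 0 fell of 15, adjusted p = 0.00041, adjusted p = 0.21 estimated, 9 and 0 adjusted over the list alone), and so did fetal-like genes (6 rose and 0 fell of 10, adjusted p = 0.00033, adjusted p = 0.45 estimated), with Clu at 76.7 ± 47.5 vs 3.88 ± 2.89. Goblet genes rose, as 6 rose and 0 fell of 12 (adjusted p = 0.0049, adjusted p = 0.56 estimated), Tff3 to 1249 ± 409 vs 342 ± 44.9 and Zg16 by 1.95 ± 0.54. So did enteroendocrine markers (3 rose and 0 fell of 6, adjusted p = 0.016, adjusted p = 0.56 estimated), Chga by 2.83 ± 0.74. Against untreated GFP cells Zg16 (1.04 ± 0.48) and Chga (0.16 ± 0.66) were not called, nor was Zg16 with quantile normalization (1.56 ± 0.59), and goblet genes stood lower in control GFP cells on doxycycline (median -1.35). The single pancreatic enzyme gene tested, Prss2, was called higher at 0.921 ± 0.713 FPKM, from 0 in the controls (lost in 3 of 5 runs). The count was 2395 (1276 up, 1119 down), or 1172 without control replicate 1.

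In GFP cells of caMEK1 colon (2 with doxycycline, 3 without) genes seen in mCherry cells were up. Psca went from 0 to 19.1 ± 13.2 FPKM (adjusted p = 4.6e-07) and Sprr2h from 0 to 10.3 ± 10.6. Pnliprp2 was at 25.6 ± 20.1 vs 1.86 ± 0.735. The complement gene C3, Ang4, Ly6g, Clca4b and Hmga1b rose by 3.07, 5.92, 3.90, 3.12 and 3.50. Ccn3 (6.69 ± 1.34 vs 109 ± 55.8), Slc30a10 (-3.27 ± 0.28), Pcdh17 (-2.32 ± 0.36) and the stem cell receptor Lgr5 (-1.41 ± 0.31) fell, with Slc16a9, Scd1, Nrp2, Prelp and Dio1 between -2.06 and -1.88. Of the sentinel genes none was called, Cdkn1a at 68.1 ± 14.1 vs 32.9 ± 4.51, adjusted p = 0.22 and Mki67 at 21.9 ± 3.9 vs 50.9 ± 8.91, adjusted p = 0.29. With carried-over RNA subtracted, Psca went from 4.16 ± 0.30 to 1.62 ± 0.23 (adjusted p = 0.0014), and Ly6g (-0.17 ± 0.90), Sprr2h (1.37 ± 0.45) and Hmga1b (3.51 ± 0.85) were no longer called. Ang4, Hmga1b and Lgr5 were lost in 4 of 5, 5 of 5 and 4 of 5 runs and with no filter. Acute phase genes were up (2 rose and 0 fell of 10, adjusted p = 0.00013, adjusted p = 0.42 estimated), Socs3 by 2.36 ± 0.35. The tests put proliferation (adjusted p = 1.6e-09, adjusted p = 0.57 estimated), with none of 33 called, and stem and Wnt genes (0 rose and 2 fell of 15, adjusted p = 5.2e-07, adjusted p = 0.57 estimated, 0 and 5 adjusted over the list alone) lower. There were 154 calls, 105 up and 49 down, 100 with voom and 427 against control GFP cells on doxycycline. Without untreated replicates 1, 2 and 3 the count was 76, 260 and 64. The groups differ in Y-linked reads too (Ddx3y 0.0484 and 0 FPKM with doxycycline, 7.95, 0.0253 and 5.28 without).

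In GFP cells of caMKK6 colon (3 and 3) the iron carrier Trf rose (95.6 ± 15.8 vs 11 ± 3.91, log2FC 3.06 ± 0.46, adjusted p = 0.0028), with the phospholipase Pla2g5 (38.3 ± 5.57 vs 6.41 ± 1.69) and C3 (11.4 ± 3.19 vs 1.33 ± 0.478). Etv4, Gstp3, the cold-inducible Rbm3 and Gsta1 rose by 1.84, 1.84, 1.75 and 1.59, and Tpm3-rs7, which resembles its parent gene, by 4.08. Slc30a10 (1.48 ± 0.799 vs 18.6 ± 1.88), Fndc5 (0.921 ± 0.258 vs 10.3 ± 1.3), the calcium binding S100g (-4.19 ± 0.89) and the mucin Muc2 (-2.02 ± 0.53, lost in 6 of 6 runs) fell, with Prap1, Hoxb6, Cmah, Cyp2c55 and Mgll between -2.62 and -2.18. Against control GFP cells on doxycycline S100g (-0.04 ± 0.99), Muc2 (-0.61 ± 0.59) and Prap1 (-1.54 ± 0.76) were not called. Etv4, Gsta1, Tpm3-rs7, S100g and Prap1 were lost in 4 of 6, 3 of 6, 3 of 6, 5 of 6 and 5 of 6 runs, and Muc2 and Prap1 with voom, no filter and quantile normalization. No sentinel gene was called (log2FC -1.23 to 0.69, adjusted p = 0.16 to 0.96). Acute phase genes were up (2 rose and 0 fell of 10, adjusted p = 0.0023, adjusted p = 0.64 estimated, 4 and 0 adjusted over the list alone). Stem and Wnt genes were down (0 rose and 2 fell of 15, adjusted p = 0.0028, adjusted p = 0.88 estimated, 0 and 3 adjusted over the list alone). The count was 300 (151 up, 149 down), with quantile normalization 199 up and 115 down, with voom 148 and against control GFP cells 809. Without doxycycline replicates 1 and 2 it was 116 and 145, and without untreated replicates 1, 2 and 3 it was 37, 139 and 31.

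In control mice (2 and 3) doxycycline changed no gene in colon GFP cells by limma or voom. Unadjusted p was below 0.05 in 1392 genes. The list tests put goblet genes lower with a median of -1.35 (adjusted p = 1.7e-07, adjusted p = 0.5 estimated, 0 and 9 adjusted over the list alone). Absorptive genes stood higher at 1.13 (adjusted p = 4.8e-08, adjusted p = 0.5 estimated) and proliferation genes lower at -0.74 (adjusted p = 6.7e-07, adjusted p = 0.57 estimated). Without doxycycline replicate 2 the count was 1447, no filter gave 6 and a pseudocount of 0.1 gave 1. The median gene moved by -0.13 log2.

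**Figure D4:**
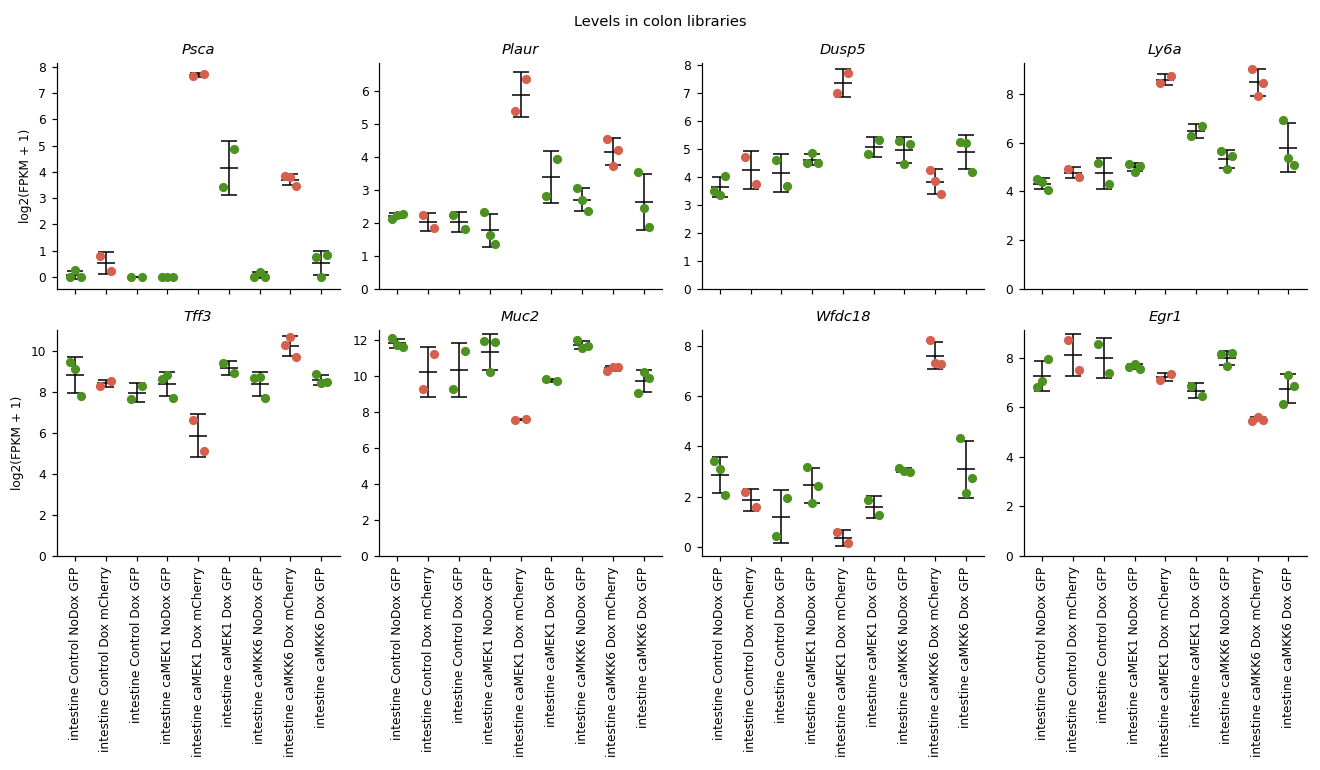
Levels in colon as log2(FPKM + 1) on the vertical axis, 1 point per library (red mCherry, green GFP), with the mean and SD of each group of 2 or 3 as black bars. Psca and Dusp5 are highest in caMEK1 mCherry cells and Wfdc18 in caMKK6 mCherry cells, while Tff3 and Muc2 are lowest in caMEK1 mCherry cells.

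Between the colours of the same caMEK1 colons (n = 2 and 2), Psca (205 ± 8.8 vs 19.1 ± 13.2, adjusted p = 4.7e-06), Ly6g (3.61 ± 0.79, lost in 2 of 4 runs) and Sprr2h (3.35 ± 0.43) were higher in mCherry cells. The lectin-like Mptx1 (76.3 ± 13.1 vs 4116 ± 251, adjusted p = 7.6e-06), Sval1 (-5.06 ± 0.53) and Clps, at 0 in mCherry cells, were lower. ERK output genes were higher (9 rose and 0 fell of 18, adjusted p = 1.9e-08, adjusted p = 0.029 estimated), with SASP genes (5 rose and 1 fell of 15, adjusted p = 1.4e-05, adjusted p = 0.075 estimated, 8 and 1 adjusted over the list alone). Goblet genes were lower (0 rose and 9 fell of 12, adjusted p = 1.5e-07, adjusted p = 0.12 estimated, 0 and 11 adjusted over the list alone), Clca1 at 82 ± 30 vs 2109 ± 160. Of 1550 calls 659 were up and 891 down, or 2607 with animal as a block. The median gene moved by -0.12 log2, median scaling gave 840 up and 642 down and quantile normalization 844 and 696, and without GFP replicate 1 or mCherry replicate 2 there were 454 and 354.

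In caMKK6 colons (n = 3 and 3) Clu (76.7 ± 47.5 vs 2.56 ± 3.03, adjusted p = 9.2e-06), Wfdc18 (4.53 ± 0.50) and Tff1 (4.27 ± 0.47) were higher in mCherry cells. Mptx1 (227 ± 50.4 vs 2317 ± 590), Aadac (-3.16 ± 0.47) and Gatm (-3.06 ± 0.33) were lower. Immediate early genes were lower (0 rose and 9 fell of 15, adjusted p = 0.00073, adjusted p = 0.6 estimated, 0 and 10 adjusted over the list alone). NRF2 targets were higher (8 rose and 1 fell of 13, adjusted p = 0.00073, adjusted p = 0.44 estimated), as were fetal-like genes (5 rose and 0 fell of 10, adjusted p = 0.00031, adjusted p = 0.44 estimated, 6 and 0 adjusted over the list alone). The lymphocyte marker Gzma was at 0 in mCherry cells and 2.69 ± 3.75 FPKM in GFP cells (called, lost in 4 of 6 runs). The count of 2463 (951 up, 1512 down) was 1547 and 1349 without mCherry replicates 2 and 3.

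In control colons (n = 2 and 2) 10 genes differed between the colours, the surface protein Igsf23 being up (11.3 ± 1.3 vs 2.44 ± 1.16, adjusted p = 0.046, lost in 3 of 4 runs). Krcc1 (25.2 ± 2.75 vs 46.6 ± 0.49, adjusted p = 0.046), Kcmf1 (-0.78 ± 0.14) and the histone demethylase Kdm1a (-0.72 ± 0.13) were down, each lost in 4 of 4 runs, and median scaling and the block lost all 4. The enteroendocrine list stood lower with none called (adjusted p = 0.001, adjusted p = 0.99 estimated). Voom called 4 genes, median scaling 3, no filter 29 and animal as a block 0. The library left out changed the count.

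Against each other, caMEK1 (n = 2) and caMKK6 (n = 3) mCherry colon cells differed. Tff3 was at 65.3 ± 44 vs 1249 ± 409, log2FC -4.36 ± 0.49, adjusted p = 8.9e-06, Wfdc18 at 0.301 ± 0.281 vs 204 ± 82.6 and Sval1 at -5.05 ± 0.48, all lower with caMEK1. Pnliprp2 (119 ± 14.1 vs 1.91 ± 1.62), Il5ra (5.28 ± 0.45) and Prss22 (4.48 ± 0.34) were higher. Cdkn1a was higher with caMEK1 (172 ± 52.6 vs 44.8 ± 11.9, adjusted p = 0.0031). Goblet genes were lower (0 rose and 10 fell of 12, adjusted p = 8.1e-08, adjusted p = 0.12 estimated). ERK output genes were higher (9 rose and 0 fell of 18, adjusted p = 5.9e-07, adjusted p = 0.074 estimated, 10 and 1 adjusted over the list alone), Dusp5 by 3.52 ± 0.39. TGF-beta genes were higher (2 rose and 0 fell of 6, adjusted p = 0.0062, adjusted p = 0.074 estimated, 5 and 0 adjusted over the list alone). Heat shock genes were lower (0 rose and 3 fell of 10, adjusted p = 0.044, adjusted p = 0.54 estimated, 0 and 4 adjusted over the list alone). Of 2389 calls 988 were up and 1401 down, and without caMEK1 replicates 1 and 2 or caMKK6 replicate 3 there were 1574, 964 and 1504.

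The mCherry and GFP comparisons within a genotype shared 64 rises and 43 falls in caMEK1 colons, where 10 and 5.9 would by chance, and 74 and 66 in caMKK6 colons, where 16.7 and 14.4 would, the animals being shared here too. Across systems, 412 genes rose with caMEK1 in both MEFs at day 7 and colon mCherry cells (289.9 by chance) and 416 in both MEFs and liver (318.1), and the falls were 317 (305.3) and 370 (335.8). For caMKK6 the rises were 188 (170.5) with colon and 506 (478.9) with liver, and the falls 217 (221.3) and 97 (140.1).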

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

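Of the tests in this part, the splits by replicate pairs, the one without caMEK1 animal 3, those of carried-over RNA and those of the transgene reads were chosen after the results were seen.

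The kinases differed by a test of the difference itself in 4287 genes at day 7 in MEFs, 3292 in liver mCherry cells and 2389 in colon mCherry cells. For the MEF difference 6 of 100 drawn splits of the 12 libraries gave as many genes, with 5317 as the highest of the others, so chance is not excluded by this test. A split that calls more genes than the real one points to a structure of the samples, here 4 groups mixed with each other. Splits that moved whole replicate pairs reached the real count in 1 of 10 cases, with 0 as the highest other, and are too few for a share under 0.05.

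The same limit of 10 splits held for comparisons of 3 libraries with 3, where 1 split, the real one, gave the count. The real counts were 4454, 6554 and 7042 for caMEK1 and 4443, 5088 and 4629 for caMKK6 at days 2, 4 and 7 in MEFs, 3989 in liver caMEK1 GFP cells and 2463 between the colours of caMKK6 colon, each with 0 as the highest other. Between the colours of caMEK1 liver the real count was 488 and the highest other 27, and in colon caMKK6 GFP cells 300 and 1.

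Acute phase genes such as Lcn2 and Saa2 were higher in liver GFP cells of caMEK1 and caMKK6 mice on doxycycline. The mCherry reporter was seen in GFP cells, at up to 18.8% of its level in mCherry cells in liver (control animal 2) and 11.8% in colon (caMEK1 animal 2), but RNA carried over from mCherry cells is argued against, since the list was lower in mCherry than in GFP cells, with a median log2FC of -0.88 in caMEK1 and -1.06 in caMKK6 mice. Doxycycline and kinase cannot be told apart: 6 members rose more in caMEK1 mice than in control mice given the higher dose, and 2 in caMKK6 mice (median difference 1.38), but all 4 Y-linked genes were below 0.5 FPKM in the control GFP cells on doxycycline and not in the untreated ones. The bound set for this test (5 members) took the change in control mice for that of doxycycline alone. Signals from kinase-bearing cells to their neighbours (not tested) and systemic stress of the animals remain open.

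Genes typical of male liver, such as Elovl3, Cyp4a12a, Hsd3b5 and Mup17, were nearly lost in caMEK1 mCherry hepatocytes and also in GFP cells (Elovl3 at -8.00 log2, in caMKK6 mice -7.68), so not only where the kinase is, and 1 of the 3 animals (replicate 3) had a female-type liver. That animal held 33.5 FPKM of Sult2a1 in mCherry and 77.4 in GFP cells, where the other 21 liver libraries reached at most 0.312. Without both of its libraries 8 of the 8 named falls were still called. These genes had been picked for groups that separated completely with animals 1 and 2 in, so that outcome was close to fixed and decides nothing. Animals 1 and 2 had Y-linked reads (Ddx3y at 3.2 and 4.13 FPKM), Sult2a1 at 0 and Elovl3 at 0.287 and 0.286 FPKM. The controls, with almost no Y-linked reads, held Elovl3 at 323 and 306 FPKM. A female-type liver therefore does not account for the loss of Elovl3 in animals 1 and 2. The kinase stays open.

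The caMEK1 transgene was listed above 5 FPKM in 5 of 12 caMKK6 MEF libraries, at up to 16.5 FPKM (day 2, replicate 2). Reads of the human MKK6 transgene given to the frog entry are argued against, since 1 caMKK6 library had 892 FPKM of the human entry and 0 of the frog one. RNA of doxycycline-treated caMEK1 cells may be the source in untreated replicates 2 and 3, where 28 genes marking those cells exceeded replicate 1 by 2.13% of their level in them (mean of 2 medians), beside 1.02% and 1.48% for the transgene. Whether cells, RNA or reads were mixed stays open. No biological explanation was tested.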

How the results depend on the processing

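Alternatives chosen after seeing the data are listed above. Of 179 counts under alternatives other than leave-one-out, 150 were within 1.5 times the reported count, 19 were lower and 10 higher. With the block within genotype, the carry-over subtraction and animal 3 left out, each count was within that range.

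With no filter the control comparisons gave 15 genes (liver GFP), 50 (liver colours), 6 (colon GFP) and 29 (colon colours), and a pseudocount of 0.1 gave 1 in colon control GFP cells. Median scaling gave 184 between the colours of caMKK6 liver, 1809 between the kinases in liver, and 4 and 3 between control colours in liver and colon. Quantile normalization gave 2462 (liver caMEK1 GFP), 5 (liver control GFP), 199 (liver caMKK6 colours), 3 (liver control colours) and 1742 (between the kinases in liver). Voom gave 2 in liver control GFP, 6 in liver control colours, 100 and 148 in colon caMEK1 and caMKK6 GFP, and 4 in colon control colours. Animal as a block gave 1277, 954 and 6 between the colours of caMEK1, caMKK6 and control liver, and 2607 and 0 between those of caMEK1 and control colon. Against control GFP cells, colon caMEK1 and caMKK6 GFP cells gave 427 and 809. The cause was not tested in these cases. Without the caMKK6 MEF libraries that list the other transgene, days 2, 4 and 7 gave 1484, 2388 and 2674, from fewer libraries.

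With 1 library left out, every MEF count and that of liver caMEK1 GFP stayed within 1.5 times. The liver ranges were 1412 to 2762 (caMEK1 mCherry), 1662 to 3904 (caMKK6 mCherry), 206 to 3950 (caMKK6 GFP), 0 to 3 (control GFP), 193 to 809, 261 to 1478 and 0 to 2 (colours of caMEK1, caMKK6 and control) and 2090 to 3671 (between the kinases). In colon they were 808 to 1936 and 1172 to 1854 (mCherry), 49 to 260, 31 to 296 and 0 to 1447 (GFP of caMEK1, caMKK6 and control), 354 to 1697, 1349 to 2522 and 2 to 20 (colours) and 964 to 2083 (between the kinases). A lone library left in a group was assumed to vary like the other groups.

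Of 595 list tests 183 passed, and 9 did with an estimated correlation. Values of genes named in the text changed sign in 2 cases, Ly6g in colon caMEK1 GFP cells with carry-over subtracted (-0.17) and Cxcl1 in liver caMEK1 GFP cells against control GFP cells (-0.82), and the cause was not tested. With changes added to simulated data, 2-fold changes were found for 92.5% of genes for MEF caMKK6 day 7, 34.3% for liver caMKK6 mCherry and 46.3% for colon caMEK1 mCherry, the comparisons simulated.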

Other observations

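Krcc1, singled out after the data were seen, was lower in control mCherry than GFP cells (log2FC -1.17 liver, -0.87 colon). The block lost both calls. The other named falls were Kcmf1, near Krcc1 on chromosome 6, and Cdc42, Camk2n1 and Kdm1a, together on chromosome 4. In liver mCherry cells the mCherry reporter stood at 7.66 ± 4.07 FPKM in caMEK1 mice (SD, n = 3) and 4356 ± 524 in control mice (n = 2). Albumin took 18.8 ± 5.01% of all FPKM in caMEK1 mCherry hepatocytes and 17.6 ± 2.05% in GFP cells on doxycycline (n = 3 each), against 9.47 ± 1.22% untreated (n = 3) and 7.17 ± 0.16% in control mCherry cells (n = 2).

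The labels call every mouse male. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were all below 0.5 FPKM in 13 of 70 libraries, 8 of 23 in liver, 5 of 23 in colon and 0 of 24 in MEFs. In liver these were both colours of both control mice on doxycycline, of caMEK1 animal 3 and of caMKK6 animal 1. In colon they were caMEK1 mCherry replicate 2, caMEK1 GFP replicates 1 and 2 on doxycycline and replicate 2 without, and caMKK6 mCherry replicate 2.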
